A study of Mus musculus with 24 samples.

How the data were processed

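RNA sequencing had been done on mouse astrocytes that lack Nf1 and p53 and serve as a cell model of glioblastoma, an aggressive brain tumour. One preparation came from male cells (Male6) and one from female cells (Female6), so sex and cell preparation cannot be told apart anywhere in these data. The 24 libraries form 8 groups of 3, named here from the sample titles: male and female cells in DMSO set 1 and under JQ1, and male and female cells in DMSO set 2 and under CPI0610. Per the labels' protocols, cells received 0.05% DMSO, JQ1 at 500 nM or CPI0610 at 1 µM for 24 hours, RNA was poly(A)-selected and libraries were made with a TruSeq mRNA kit for an Illumina HiSeq instrument. Both compounds inhibit BET bromodomain proteins, chromatin readers of acetylated histones.

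The authors deposited 2 tables of raw read counts per gene and 2 matching tables of RPKM, one of each for JQ1 with DMSO set 1 and one of each for CPI0610 with DMSO set 2. The count tables hold whole numbers that are not normalized, per the file headers and the values. The RPKM values in the deposited tables are counts divided by gene length and by the column total: over 23008 genes of the JQ1 table and 21414 of the CPI0610 table, one length per gene explained every library to within 0.1%, which held for 100% of these genes. STAR 2.7.0, HTSeq 0.11.1 and the mouse build mm10 are named in the submitters' processing notes, with no role given. The annotation, the treatment of reads that map to several genes, and whether counting used the strand are not given in the sources used here. Because of the last 2 points, genes that share sequence or overlap another gene are reported as uncertain.

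Columns of the CPI0610 table matched single samples by name. Columns of the JQ1 table gave the group, a run number and a month, and the run numbers are in no title, so these libraries stand as replicates of their group and are called July-1, July-2 and May after the column suffix (2 dated July and 1 dated May in each group). The DMSO columns beside CPI0610 are taken as set 2 because the others are named set 1 and the labels hold no other set. There were 0 columns of values outside this mapping and 0 rows that name no gene. Library totals were 26592589 to 41529627 counts in the JQ1 table, which lists 41388 genes, and 12460427 to 28373949 in the CPI0610 table, which lists 38561 genes. Both tables list 37520 genes in common. Symbols were matched by Ensembl identifier to the GENCODE annotation of mm10 used here as a reference, for 40254 genes of the JQ1 table and 36639 of the CPI0610 table.

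No pair of libraries was identical (0 pairs), and libraries of one group differed by a chi-square per gene of 2.08 to 159, so each was counted as a replicate. Nothing in the labels says whether replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical. Floors, used for genes without counts in a group, cover counting error only. The ± values also hold the spread between libraries.

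Within each table, genes were kept by edgeR's filterByExpr at a minimum count of 10, scaled by TMM and tested with edgeR's quasi-likelihood test (glmQLFit with robust estimation, glmQLFTest), with 1 dispersion trend shared by the 4 groups of the table. The comparisons were each drug response in each sex, the sex difference of the response (female response minus male response), and female against male in DMSO and under each drug. A fit of all 24 libraries over genes in both tables gave the JQ1 response minus the CPI0610 response in each sex, and the difference of the 2 DMSO sets. Each response was taken against its own DMSO set, so the responses to JQ1 and CPI0610 share no control libraries. P-values were adjusted by Benjamini-Hochberg over the genes tested, and genes were called at an adjusted p under 0.05. Counts with at least a 2-fold change are also given. The ± values after log2 fold changes are approximate standard errors, with 3 libraries per group. Each is the size of the log2 fold change divided by the square root of edgeR's quasi-likelihood F. They are rough, and may be too small, where a group holds few counts. Levels are CPM, counts scaled to a common library total after TMM, with the SD over 3 libraries. Tools were R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.

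The comparisons, tests, alternatives, gene lists and the rule for named genes were set before the data were examined, except where the text says otherwise. The 31 gene lists were BET inhibitor induced genes, BET inhibitor repressed genes, BET proteins and P-TEFb partners, S phase genes, G2/M genes, CDK inhibitors and G1 regulators, ribosome biogenesis genes, cytosolic ribosomal protein genes, immediate early and AP-1 genes, NF-kB and cytokine genes, interferon-stimulated genes, antigen presentation genes, extracellular matrix genes, TGF-beta and YAP response genes, integrin genes, matrix protease genes, sterol synthesis genes, unfolded protein and integrated stress response genes, p53 target genes, glycolysis and hypoxia genes, lysosome and autophagy genes, glioma stem cell and neurodevelopmental factors, markers of astrocytes, neurons, oligodendrocyte lineage, microglia and macrophages, endothelium, and fibroblasts and mural cells, Y-linked genes, X-inactivation and X-escape genes, and mitochondrially encoded genes. Each was tested with limma's camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, adjusted over the 31 lists. The fry test of the sets of sex-biased genes was adjusted over the 2 sets of a table, an adjustment added after the values were seen. List p-values in the text are camera's adjusted p at the preset correlation unless said otherwise.

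Named genes are, for each drug response and for female against male in DMSO, the 6 with the largest positive and the 6 with the largest negative log2 fold change among genes called, with an average log2 CPM of at least 2 and no overlap of the groups' values. For each sex difference of a response they are 5 in each direction, without the last condition. Up to 3 members with the smallest adjusted p were added per list, together with Nf1, Trp53, Brd2, Brd3, Brd4, Hexim1, Myc, Cdkn1a, Xist, Ddx3y, Eif2s3y, Kdm5d and Uty. Genes named only by a Gm number, a Rik clone or an identifier were skipped. Sequence sharing was measured as the share of a gene's exonic 50-mers (windows of 50 bases) found in another gene.

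Replicate numbers of the CPI0610 table did not pair the libraries: 2 of 18 same-numbered pairs had correlated deviations over 0.1. Libraries of the JQ1 table did deviate together by month. All 30 same-month pairs correlated at 0.24 to 0.82, while pairs from different months lay between -0.72 and -0.32. A fit with the month as a block, and one of the July libraries alone, were therefore added after the data were seen, and are given in part. A block of the number and month in the column names was also added then. Other alternatives were scaling by DESeq2's size factors or by library totals, no filter or a mean of at least 1 CPM, DESeq2, limma on log2(RPKM + 1) and log2(RPKM + 0.1), fits of only the groups compared, a replicate block, an adjusted p of 0.01, and leaving out each library in turn. The edgeR steps were tested on simulated data with 200 changed genes. Of genes changed 2-fold and 4-fold, 72% and 95% were recovered for the JQ1 response in male cells (14732 genes). For its sex difference the shares were 16% and 89%. For CPI0610 (13594 genes) they were 98% and 100%, and 85% and 99%. For the JQ1 against the CPI0610 response in male cells (14987 genes) they were 58% and 97%. False calls were 4.57%, 2.78%, 7.48%, 7.54% and 2.52% of calls in that order. Shares were not split by level, and both hold for this simulation only.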

Results

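Poly(A) RNA was sequenced from male and female mouse astrocytes labelled as lacking Nf1 and p53, a cell model of glioblastoma, after 24 hours with a BET bromodomain inhibitor or with the solvent DMSO. The series asks how far Brd4, a BET protein that binds acetylated chromatin at enhancers, takes part in differences between male and female tumour cells. The data hold 8 groups of 3 libraries, with 26592589 to 41529627 counts per library in the JQ1 table and 12460427 to 28373949 in the CPI0610 table. The lowest totals belonged to female CPI0610 replicates 2 and 3, at 12866574 and 12460427. In the JQ1 table the first principal component separated male from female cells (50.6% of variance), the second DMSO from JQ1 (23.9%) and the third the May from the July libraries (15.1%). In the other table sex took 63% and drug 22.8%, and the third component (5.35%) spread the female libraries, from female DMSO 2 replicate 2 (-29.4) and female CPI0610 replicate 1 (-28.8) to female CPI0610 replicate 3 (35.1).

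The genes for what the cells are labelled as lacking, Nf1 (a Ras inhibitor, ENSMUSG00000020716, chromosome 11, 79339693 to 79581612, plus strand in mm10) and Trp53 (the gene for p53, ENSMUSG00000059552, chromosome 11, 69580359 to 69591873, plus strand), gave counts in every group. No unedited cells are among these samples, so neither level checks the genotype, and a count over the whole gene cannot show a deletion of part of it. Nf1 stood at 87.3 ± 4.54 CPM (counts scaled to a common library total; SD, n = 3) in male DMSO 1, 59.7 ± 4.97 under JQ1, 64.2 ± 8.16 in female DMSO 1 and 41.7 ± 3.55 under JQ1. In the CPI0610 table it stood at 48.5 ± 3.19 and 39 ± 0.89 in male and at 67.6 ± 5.64 and 59 ± 6.01 in female cells, DMSO first. Trp53 stood at 621 ± 150, 1080 ± 402, 701 ± 122 and 666 ± 124 CPM in the same order of the JQ1 table. In the CPI0610 table it stood at 1140 ± 62.4 and 2380 ± 59.8 in male cells and at 693 ± 110 and 813 ± 350 in female cells. Nf1 fell 1.46-fold in male and 1.54-fold in female cells with JQ1 (edgeR adjusted p = 0.0028 and 0.0017). Trp53 rose 2.09-fold with CPI0610 in male cells (edgeR adjusted p = 0.0025) and did not pass the test with CPI0610 in female cells (0.45). With JQ1 in male cells the Trp53 call (log2 0.81 ± 0.28, adjusted p = 0.04) was lost without male DMSO 1 July-2 or May or male JQ1 July-1 or July-2, with an adjusted p of up to 0.19. The Nf1 call with CPI0610 in male cells (-0.31 ± 0.092, adjusted p = 0.015) was lost without male DMSO 2 replicate 2 or 3 or male CPI0610 replicate 2, at an adjusted p of up to 0.062.

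**Figure D1:**
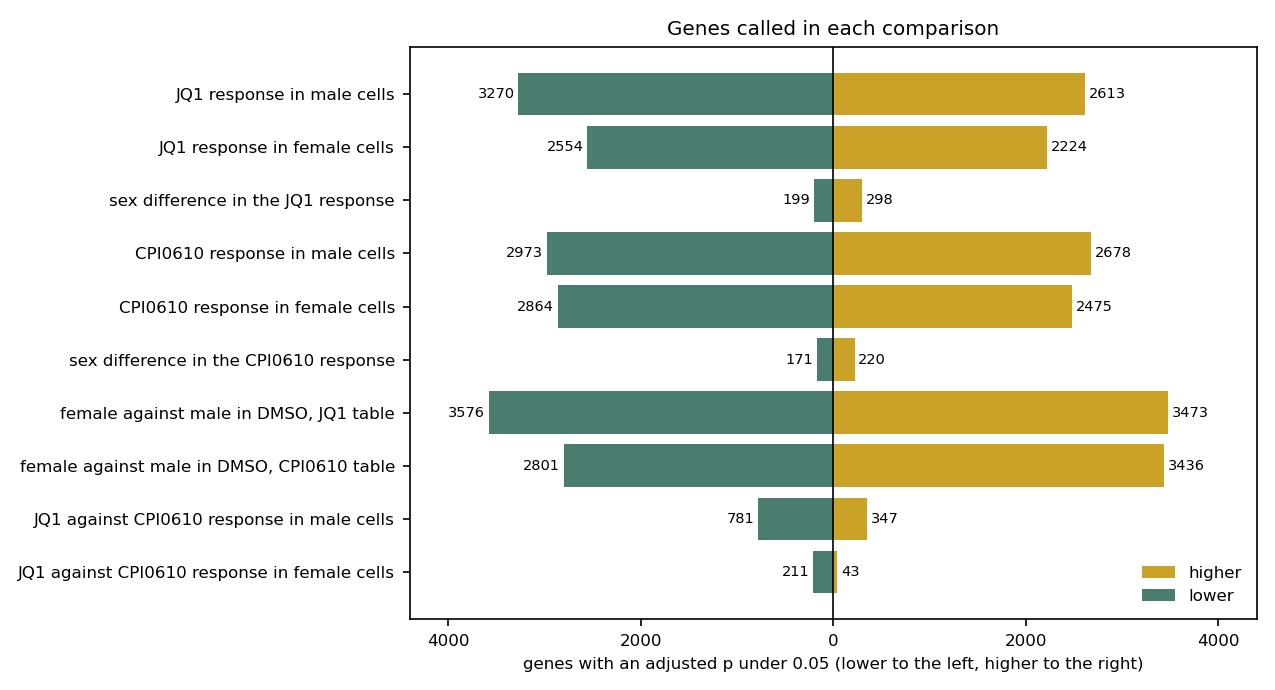
Number of genes called by edgeR at an adjusted p under 0.05 in each of 10 comparisons (x axis: number of genes, lower to the left and higher to the right; y axis: comparison). The responses to each drug held 2613 and 3270 genes up and down in male cells with JQ1 and 2678 and 2973 with CPI0610, against 298 and 199 and 220 and 171 for the sex differences of the responses.

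The first comparison asked what JQ1 changed in male cells. Linker histone Hist1h1c rose 5.99-fold (log2 2.58 ± 0.17, adjusted p = 4.4e-06), Hexim1, the inhibitor of the elongation kinase P-TEFb (ENSMUSG00000048878, chromosome 11, 103116231 to 103119725, plus strand), rose 2.7-fold, and the BET gene Brd2 (chromosome 17, 34112023 to 34122634, minus strand) rose 3.24-fold. Collagen VI gene Col6a3 (chromosome 1, 90765923 to 90843971, minus strand) fell 125-fold, from 133 to 1.07 CPM, and Col3a1 fell 22.9-fold. Cdkn1a, which encodes the cell cycle inhibitor p21 (chromosome 17, 29090976 to 29100727, plus strand), fell 3.69-fold (-1.88 ± 0.21, adjusted p = 5.8e-05). Of 14732 genes tested by edgeR, 2613 rose and 3270 fell, 392 and 2086 of them by at least 2-fold. With library totals instead of TMM, the median of all genes moved to -0.12 and the share of calls that rose went from 44.4% to 29.3%, so changes under about 0.1 on the log2 scale have no settled direction.

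Among the strongest JQ1 responses in male cells, Fam222a rose 34.8-fold, from 36 to 1287 summed counts, and the histone gene Hist1h4i rose 7.36-fold. Galnt15, a glycosyltransferase, fell 106-fold, Igfbp5, which binds insulin-like growth factors, fell 101-fold and the organic anion transporter Slco1a5 fell 64.9-fold. Without male DMSO 1 July-1 Fam222a gave 6.04 on the log2 scale against 5.12, and without male JQ1 July-1 Slco1a5 gave -6.99 against -6.02 and Col6a3 -7.63 against -6.97. Of the BET family, Brd4 (log2 0.49, adjusted p = 0.1) did not pass the test, although it did with the month as a block and in the July libraries alone. Brd3 was called (0.43, adjusted p = 0.012) but lost without male JQ1 July-1 or July-2, at up to 0.062. Myc, a cell growth factor often lowered by BET inhibitors, stood at 71.3 CPM in DMSO and 57 under JQ1 and did not pass the test (-0.32 ± 0.21, adjusted p = 0.24). Hist1h4i and Hist1h2bc share 28.9% and 30.6% of their 50-mers with other genes, so their counts are uncertain.

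Gene lists placed these changes in groups. Of 9 BET inhibitor induced genes 6 rose and 0 fell (7 and 0 adjusted over the list alone), with a median of 1.43 (camera adjusted p = 9.64e-06), and the call held at an adjusted p = 0.031 with an estimated correlation. Of 15 BET inhibitor repressed genes 8 fell (8 adjusted over the list alone, adjusted p = 0.016), among them the G1 kinase Cdk6, which fell 4.76-fold, and the AP-1 gene Fosl1, which shares 52.6% of its 50-mers. The list's adjusted p = 0.374 with an estimated correlation. BET proteins and P-TEFb partners rose in 12 of 21 members and fell in 1 (12 and 1 adjusted over the list alone, adjusted p = 0.000433), and adjusted p = 0.242 with an estimated correlation. S phase genes fell in 28 of 40 members (30 adjusted over the list alone, median -1.25, adjusted p = 3.24e-05), among them Uhrf1, a DNA methylation factor that fell 3.94-fold and shares 15.4% of its 50-mers. G2/M genes fell in 34 of 48 (37 adjusted over the list alone, median -1.12, adjusted p = 3.83e-07), among them the spindle gene Psrc1 (6.19-fold) and cyclin Ccnb2 (3.13-fold). These cell cycle calls were lost, at adjusted p = 0.621 for S phase and 0.539 for G2/M with an estimated correlation. CDK inhibitors and G1 regulators rose in 2 and fell in 10 of 21 (3 and 12 adjusted over the list alone, adjusted p = 0.00722), with adjusted p = 0.374 with an estimated correlation.

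Interferon-stimulated genes fell in 16 of 25 members (20 adjusted over the list alone, median -1.64, adjusted p = 1.7e-08), among them Parp9 (6.25-fold), Bst2 (5.11-fold) and Ifit2 (2.93-fold), with adjusted p = 0.242 with an estimated correlation. NF-kB and cytokine genes fell in 10 of 19 and rose in 2 (11 and 2 adjusted over the list alone, adjusted p = 0.0141), led by the chemokine Ccl2, which fell 8.11-fold, with adjusted p = 0.4 with an estimated correlation and 0.0619 in the July libraries. Sterol synthesis genes fell in 19 of 25 and rose in 0 (21 and 0 adjusted over the list alone, median -0.80, adjusted p = 2.64e-06), and adjusted p = 0.242 with an estimated correlation. Among them Stard4, a cholesterol carrier, fell 2.95-fold, Cyp51 fell 2.21-fold and Hmgcs1, the synthase that makes HMG-CoA (ENSMUSG00000093930, chromosome 13, 119690379 to 119708260, plus strand), fell 2.14-fold. Hmgcs1 shares 11.6% of its 50-mers, and 12.1% of its exons overlap a gene on the other strand. Extracellular matrix genes fell in 14 and rose in 4 of 32 (14 and 5 adjusted over the list alone, median -0.36, mean -1.31, adjusted p = 0.00691). Integrin genes fell in 10 and rose in 1 of 19 (10 and 1 adjusted over the list alone, adjusted p = 0.00305) and matrix proteases fell in 7 and rose in 1 of 20 (7 and 1 adjusted over the list alone, adjusted p = 0.016). With an estimated correlation these gave adjusted p = 0.4, 0.287 and 0.242. Itgb3, a vitronectin receptor chain, fell 10.8-fold and the gelatinase Mmp2 fell 8.83-fold. Lysosome and autophagy genes rose in 11 and fell in 4 of 34 (15 and 4 adjusted over the list alone, adjusted p = 0.03), with adjusted p = 0.634 with an estimated correlation.

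Markers of several brain cell types fell with JQ1 in male cells. Of 20 astrocyte markers 13 fell and 1 rose (14 and 1 adjusted over the list alone, median -1.97, adjusted p = 0.000387, and adjusted p = 0.326 with an estimated correlation), among them the glutamate transporter Slc1a2, which fell 6.04-fold. Oligodendrocyte lineage markers fell in 5 of 9 (5 adjusted over the list alone, adjusted p = 0.00518, and adjusted p = 0.242 with an estimated correlation), among them the growth factor receptor Pdgfra (4.42-fold). Fibroblast and mural cell markers fell in 8 and rose in 1 of 14 (8 and 1 adjusted over the list alone, adjusted p = 0.016, and adjusted p = 0.4 with an estimated correlation), and this call ended in the July libraries at 0.0619. Microglia and macrophage markers fell in 3 of 6 (3 adjusted over the list alone, adjusted p = 0.0309), led by Tmem119 (17.8-fold), with adjusted p = 0.242 with an estimated correlation, 0.0514 with the month block and 0.0619 in the July libraries. Lists that were not called were immediate early genes (11 up, 6 down of 30, adjusted p = 0.0559, but 0.0256 with the month block and 0.000167 in the July libraries), TGF-beta and YAP response genes (9 up, 3 down of 28, adjusted p = 0.0732, but 0.0293 in the July libraries), endothelial markers (0.0875) and mitochondrially encoded genes (0.0875). Others without a call were antigen presentation genes (0.231), neuron markers and glycolysis genes (0.421 each) and X-inactivation genes (0.544). The p53 targets (6 up, 7 down of 26), ribosome biogenesis genes and ribosomal protein genes gave 0.713 each, stress response genes and Y-linked genes 0.76 each. Glioma stem cell factors gave 0.855, with a median of -0.05 and a mean of -0.11 although the test's direction was up.

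**Figure D2:**
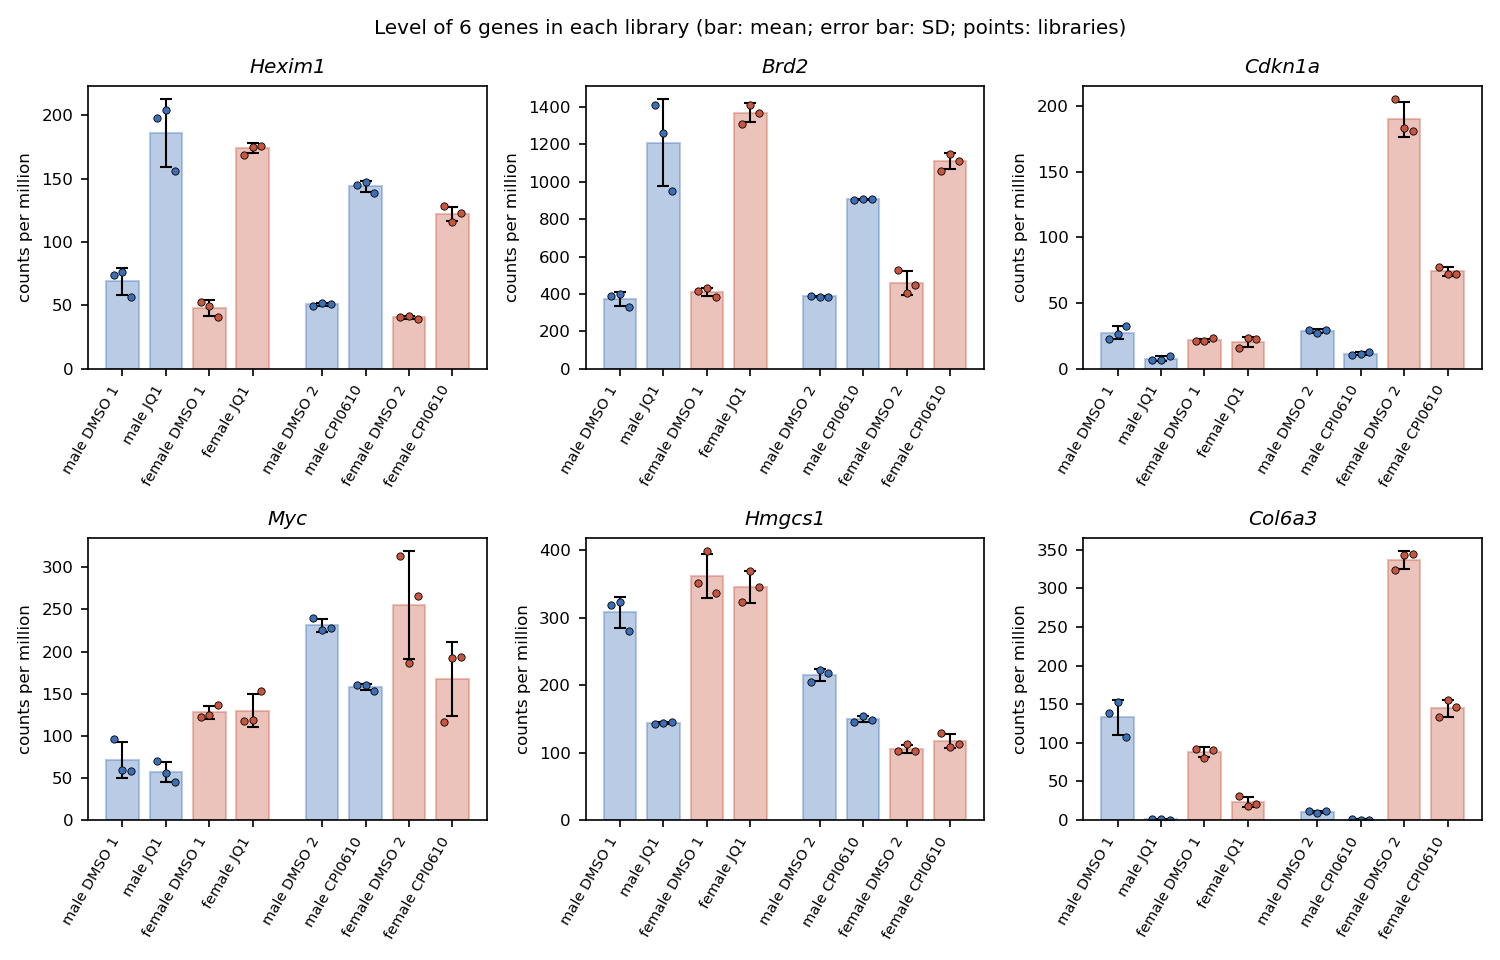
TMM-scaled CPM (y axis, linear, from 0) of Hexim1, Brd2, Cdkn1a, Myc, Hmgcs1 and Col6a3 in the 8 groups (x axis), with male cells in blue and female cells in red. Bars are means, error bars SD and points the 3 libraries of each group. Cdkn1a stood at 21.5 in female DMSO 1 and at 20.4 under JQ1, and at 190 in female DMSO 2 and at 74 under CPI0610.

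JQ1 was then compared with DMSO in female cells. Hist1h1c rose 7.08-fold (2.82 ± 0.17, adjusted p = 5.1e-06), Hexim1 rose 3.63-fold and Brd2 rose 3.33-fold. The transporter gene Slco1a5 fell 37.9-fold and Has2, which makes hyaluronan, fell 25.9-fold (-4.69 ± 0.38, adjusted p = 1.7e-05). The major histocompatibility genes H2-K1 and H2-D1 rose 4.62-fold and 3.13-fold, and H2-D1 shares 12.8% of its 50-mers with other genes. Cdkn1a (-0.08 ± 0.2, adjusted p = 0.83) and Myc (0.02 ± 0.21, adjusted p = 0.96) did not pass the test. In all, 2224 genes rose and 2554 fell by edgeR, 496 and 1410 of them by at least 2-fold. With library totals the all-gene median was -0.13 and the share that rose went from 46.5% to 33.4%.

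Further JQ1 responses in female cells were Fam222a (14.8-fold higher), Hist1h4i (11.9-fold) and Hist1h2bc (5.83-fold). The water channel gene Aqp5 fell 30.7-fold, Gli1, a Hedgehog target, fell 25.2-fold (log2 -4.65, and -3.53 without female DMSO 1 July-1) and the cadherin gene Cdh26 fell by 4.56 on the log2 scale. BET inhibitor induced genes rose in 7 of 9 members (8 adjusted over the list alone, median 1.86, adjusted p = 4.87e-08), and adjusted p = 0.00739 with an estimated correlation. Lysosome and autophagy genes rose in 24 of 34 and fell in 2 (25 and 2 adjusted over the list alone, median 0.62, adjusted p = 2.94e-07), among them the proton pump gene Atp6v1h (1.6-fold) and the protease gene Ctsd (1.95-fold), 34.4% of whose exons overlap another gene. The lysosome list's adjusted p = 0.474 with an estimated correlation. Interferon-stimulated genes fell in 16 and rose in 1 of 25 (17 and 1 adjusted over the list alone, median -1.57, adjusted p = 1.52e-06), led by Parp9 (8.03-fold), with adjusted p = 0.449 with an estimated correlation. Immediate early genes rose in 16 and fell in 3 of 30 (16 and 4 adjusted over the list alone, adjusted p = 0.00432, and adjusted p = 0.449 with an estimated correlation).

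Other lists called in female cells with JQ1 were G2/M genes (5 of 48 fell, 1 adjusted over the list alone, adjusted p = 0.00432) and fibroblast markers (7 of 14 fell, 8 adjusted over the list alone with 1 up, adjusted p = 0.00432). So were extracellular matrix genes (13 fell, 4 rose, 14 and 4 adjusted over the list alone, adjusted p = 0.0139), integrins (8 fell, 1 rose, adjusted p = 0.0152) and BET proteins and P-TEFb partners (7 rose, 2 fell, 7 and 2 adjusted over the list alone, adjusted p = 0.0234). NF-kB genes (10 fell, 4 rose, 11 and 4 adjusted over the list alone, adjusted p = 0.0262), matrix proteases (6 fell, 2 rose, 7 and 3 adjusted over the list alone, adjusted p = 0.0265) and mitochondrially encoded genes (4 of 12 rose, 4 adjusted over the list alone, adjusted p = 0.0347) were called too. With an estimated correlation they gave, in the same order, adjusted p = 0.819, 0.474, 0.551, 0.449, 0.449, 0.551, 0.449 and 0.66. Sterol synthesis genes were not called: 1 rose and 1 fell of 25 (1 and 1 adjusted over the list alone), with a median of 0.06, a mean of -0.04 and adjusted p = 0.749. S phase genes (0.174), BET inhibitor repressed genes (0.137), ribosome biogenesis genes (0.0546), astrocyte markers (0.0546), oligodendrocyte markers (0.125), CDK inhibitors (0.404) and endothelial markers (0.415) were not called. The same held for microglia markers, X-inactivation genes and p53 targets (0.457 each), Y-linked genes (0.487), TGF-beta genes (0.553), glycolysis genes (0.561) and stress response genes (0.664). Nor were neuron markers and antigen presentation genes (0.817 each), glioma stem cell factors (0.927) and ribosomal protein genes (0.973), in which the median, the mean or the test differed in sign.

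The sex difference of the JQ1 response asks where female cells moved more or less than male cells. Col6a3 fell 125-fold in male cells but from 88 to 23.5 CPM in female cells, a difference of 5.06 ± 0.53 on the log2 scale (edgeR adjusted p = 0.0017). Cdkn1a, which fell in male cells, differed by 1.81 ± 0.28 (adjusted p = 0.0083). Hexim1 (0.43 ± 0.2, adjusted p = 0.32), Brd2 (0.04 ± 0.19, 0.97) and Myc (0.35 ± 0.29, 0.63) did not pass the test of the difference, with standard errors that leave differences of this size open. Sterol synthesis genes gave a median difference of 0.77: 9 of 25 were higher in the female than in the male response and 0 lower (16 and 0 adjusted over the list alone, adjusted p = 2.41e-14), among them Lss (1.4 ± 0.17), Hmgcs1 (1.04 ± 0.14) and Cyp51 (0.96 ± 0.15). The list's adjusted p = 0.218 with an estimated correlation.

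Of 14732 genes, 298 were higher and 199 lower in the female than in the male JQ1 response, and simulated 2-fold differences were found in only 16% of cases. With the month as a block 1629 genes were called, including 496 of these 497, and the July libraries gave 560 with 331 in common. Leaving out 1 library gave 207 (female JQ1 July-2), 213 (female DMSO 1 July-2), 215 (male DMSO 1 July-2), 235 (male JQ1 July-2), 241 (female JQ1 July-1), 257 (female DMSO 1 July-1) or 297 (female DMSO 1 May), and up to 683 for the rest. Beyond Col6a3, the largest differences were Rnase4 (5.06), with 13.4% of its exons in overlap with another gene, Lgals9, a galectin (4.19), and the ephrin receptor Epha3 (3.5), all higher in the female response. The nuclear receptor Nr2f1 (-2.57), the plasminogen activator Plau (-2.45), Mylk (-2.36), Fhod3 (-2.25) and Adamtsl1 (-2.21) were lower. Adcy8 (4.11 ± 0.7, adjusted p = 0.042) was lost in most runs that left out a library and turned to -0.552 in limma on log2(RPKM + 1), and Mylk was lost without male JQ1 July-2 or female DMSO 1 July-1 or July-2, at up to 0.057. Without male JQ1 July-2 Lgals9 gave 5.11, and without male JQ1 July-1 Col6a3 gave 5.71.

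Other lists of the JQ1 sex difference were called upward with few single calls. S phase genes had a median of 0.86 with 0 of 40 called (adjusted p = 7.74e-05) and G2/M genes a median of 0.56 with 0 of 48 called (adjusted p = 0.000712). With an estimated correlation they gave adjusted p = 0.601 and 0.603. Lysosome genes (1 up, 2 adjusted over the list alone, adjusted p = 0.000279), antigen presentation genes (3 up, 4 adjusted over the list alone, adjusted p = 0.00536) and CDK inhibitors (3 up, adjusted p = 0.00935) followed. Weaker calls were microglia markers (1 up, 3 adjusted over the list alone, adjusted p = 0.0116), glycolysis genes (1 up, adjusted p = 0.0246), extracellular matrix genes (4 up, 7 up and 2 down adjusted over the list alone, adjusted p = 0.0295), interferon-stimulated genes (1 up, adjusted p = 0.0354) and integrins (1 up, 4 up and 1 down adjusted over the list alone, adjusted p = 0.0443). Ribosome biogenesis genes had a median of -0.23 with 0 called (adjusted p = 0.0443). In the same order these 9 lists gave adjusted p = 0.514, 0.491, 0.491, 0.296, 0.491, 0.514, 0.55, 0.491 and 0.677 with an estimated correlation. With the month block interferon genes (0.06) and ribosome biogenesis genes (0.0663) were not called and BET inhibitor induced genes were (0.103 to 0.0263). In the July libraries ribosome biogenesis genes (0.193) and integrins (0.13) were not called. BET inhibitor repressed genes (0.0718 to 0.0481), TGF-beta genes (0.0718 to 0.0218) and Y-linked genes (0.0718 to 0.0365) were called there. No other list was called in the JQ1 sex difference, and fibroblast markers (adjusted p = 0.895) had a median of 0.22 and a mean of 0.32 although the test's direction was down.

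**Figure D3:**
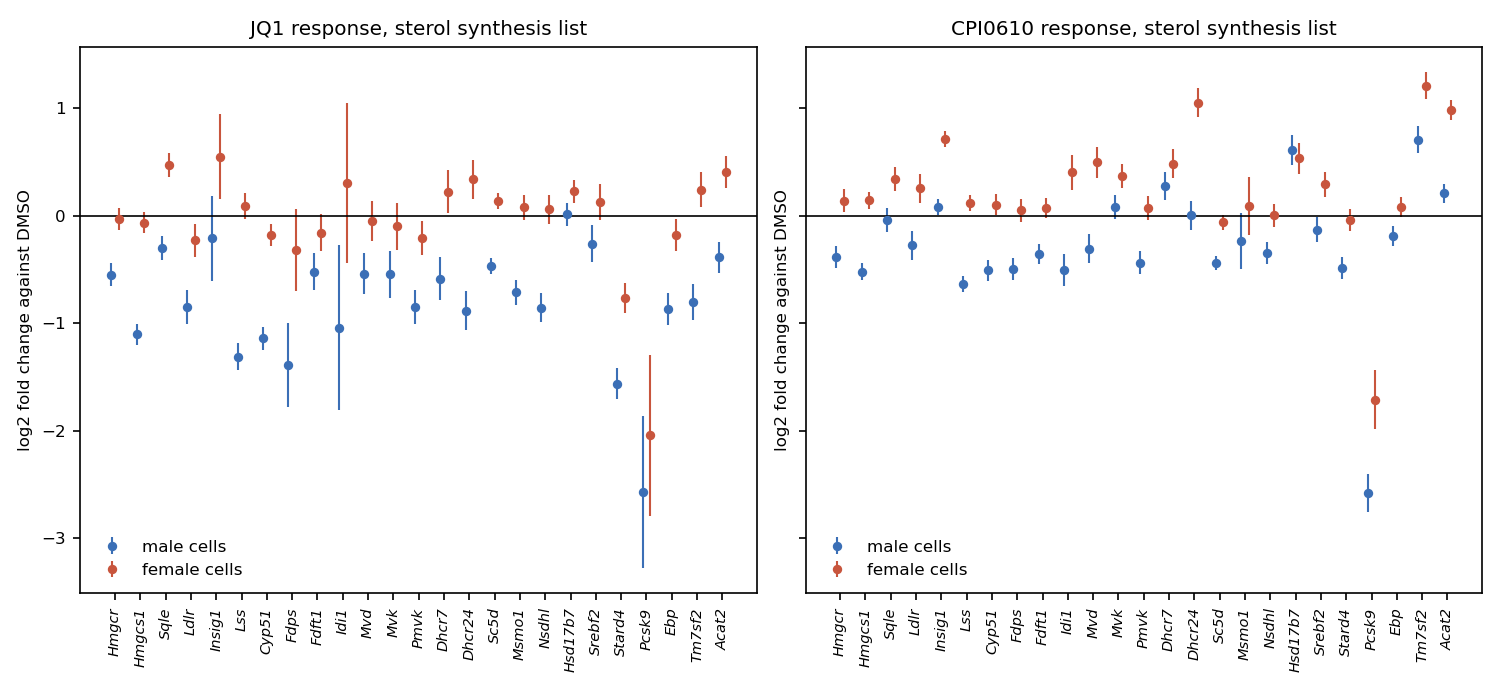
Log2 fold change against DMSO (y axis) of each measured member of the sterol synthesis list (x axis) with JQ1 (left) and CPI0610 (right), male cells in blue and female cells in red. Points are edgeR estimates and error bars approximate standard errors derived from edgeR's F, from 3 libraries per group. The list's median was -0.80 in male and 0.06 in female cells with JQ1 and -0.31 and 0.15 with CPI0610.

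CPI0610, a BET inhibitor given at 1 µM where JQ1 was given at 500 nM, was compared with its own DMSO set in male cells. Hist1h1c rose 5.52-fold (2.47 ± 0.14, adjusted p = 8.4e-08), Hexim1 2.82-fold, Brd2 2.35-fold and Txnip, a thioredoxin inhibitor, 5.57-fold. Col3a1 fell 17.2-fold (-4.1 ± 0.14, adjusted p = 2.3e-09), Col6a3 14.9-fold and Cdkn1a 2.55-fold. Txnip shares 15.7% of its 50-mers and Angpt1, named below, 13.3%. Of 13594 genes tested by edgeR 2678 rose and 2973 fell, 488 and 1013 of them by at least 2-fold. Myc was called (-0.55 ± 0.19, adjusted p = 0.036) but lost in every run without one of the 6 libraries, at an adjusted p of up to 0.091. Brd3 (0.07, 0.47) and Brd4 (0.16, 0.56) did not pass the test.

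The strongest CPI0610 responses in male cells included Stmn4, a microtubule regulator (25.8-fold higher), Fam222a (7.67-fold), the endothelial and immune transcription factor Klf2 (6.24-fold) and Gch1, an enzyme of tetrahydrobiopterin synthesis (2.49 on the log2 scale). The interleukin 33 receptor Il1rl1 fell 41.8-fold, the cornified envelope gene Sprr1a 41.4-fold, Cdh26 31.7-fold and the angiopoietin gene Angpt1 23.2-fold. BET inhibitor induced genes rose in 8 of 8 members (8 adjusted over the list alone, median 2.24, adjusted p = 1.72e-14), and adjusted p = 0.0029 with an estimated correlation. Ribosome biogenesis genes fell in 30 of 36 members (31 adjusted over the list alone, median -0.58, adjusted p = 1.16e-08), among them the pseudouridine synthase Dkc1 (1.84-fold) and Wdr43 (1.65-fold), and adjusted p = 0.0157 with an estimated correlation. Lysosome and autophagy genes rose in 22 of 34 and fell in 3 (median 0.45, adjusted p = 8.98e-06, and adjusted p = 0.0157 with an estimated correlation), among them the autophagosome gene Map1lc3b (2.07-fold) and the proton pump gene Atp6v0d1 (1.82-fold). Ribosomal protein genes fell in 18 of 43 (20 adjusted over the list alone, median -0.36, adjusted p = 0.0142, and adjusted p = 0.371 with an estimated correlation), and Rps6 among them shares 43.8% of its 50-mers.

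Extracellular matrix genes fell in 15 members and rose in 5 with CPI0610 in male cells (adjusted p = 0.000485), and NF-kB genes fell in 11 of 17 and rose in 2 (12 and 2 adjusted over the list alone, adjusted p = 0.00223). BET inhibitor repressed genes fell in 9 of 14 and rose in 2 (9 and 3 adjusted over the list alone, adjusted p = 0.0104). S phase genes fell in 16 (adjusted p = 0.0177) and G2/M genes in 12 (11 adjusted over the list alone, adjusted p = 0.0322), with medians of -0.25 and -0.16. Immediate early genes rose in 11 and fell in 8 (15 and 9 adjusted over the list alone, adjusted p = 0.0249), and BET proteins and P-TEFb partners rose in 7 and fell in 2 (8 and 2 adjusted over the list alone, adjusted p = 0.031). Interferon-stimulated genes fell in 8 of 19 and rose in 1 (adjusted p = 0.031) and fibroblast markers fell in 7 of 12 and rose in 1 (8 and 1 adjusted over the list alone, adjusted p = 0.0479). With an estimated correlation these 9 lists gave, in that order, adjusted p = 0.188, 0.0575, 0.342, 0.283, 0.455, 0.428, 0.273, 0.152 and 0.333. Sterol synthesis genes fell singly in 12 and rose in 2 of 25, but the list was not called (adjusted p = 0.0565, median -0.31). Hmgcs1 fell 1.43-fold and Pcsk9, which degrades the LDL receptor, fell 6-fold. Further lists without a call were CDK inhibitors, TGF-beta genes and integrins (0.211 each), oligodendrocyte markers (0.126), X-inactivation genes (0.265), stress response genes (0.475), Y-linked genes (0.55) and mitochondrially encoded genes (0.623). The same was true of p53 targets (8 up, 11 down, 0.659), matrix proteases (0.67), antigen presentation genes (0.702), astrocyte markers (0.75), neuron and microglia markers (0.806 each), glycolysis genes and glioma stem cell factors (0.88 each) and endothelial markers (0.989). In astrocyte and neuron markers the test's direction was up with a negative median, and in glioma stem cell factors the median was 0.04 and the mean -0.19.

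In female cells CPI0610 raised Hexim1 3.02-fold (1.59 ± 0.066, adjusted p = 1.5e-08), Brd2 2.41-fold and Hist1h1c 4.95-fold, and Gch1 rose 10.2-fold. Igfbp5 fell 15.3-fold (-3.94 ± 0.13, adjusted p = 6e-09), the BMP antagonist Grem1 14.5-fold and Has2 12.3-fold. Cdkn1a fell 2.56-fold, from 190 to 74 CPM, and Col6a3 fell 2.33-fold. Sprr1a (-3.87, but -3.01 and -4.62 without female CPI0610 1 or 3), Tnnt2 (-3.71) and Il1rl1 (-3.61) fell. Myc was called (-0.62 ± 0.19, adjusted p = 0.023) but lost without female DMSO 2 replicate 1 or 3, at an adjusted p of up to 0.11. By edgeR 2475 genes rose and 2864 fell, 428 and 891 of them by at least 2-fold. Fitting only the groups compared gave 3305 calls, and library totals moved the all-gene median to -0.1.

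BET inhibitor induced genes rose in 8 of 8 in female cells with CPI0610 (8 adjusted over the list alone, median 1.6, adjusted p = 2.9e-15), ribosome biogenesis genes fell in 29 of 36 (31 adjusted over the list alone, median -0.57, adjusted p = 2.96e-10) and lysosome genes rose in 22 and fell in 3 of 34 (median 0.45, adjusted p = 1.5e-07). These calls held, at adjusted p = 0.00659, 0.016 and 0.00725 with an estimated correlation. Sterol synthesis genes rose in 9 and fell in 1 of 25 (9 and 1 adjusted over the list alone, median 0.15, adjusted p = 0.00643, and adjusted p = 0.154 with an estimated correlation), among them Tm7sf2, a sterol reductase (2.31-fold), Acat2 (1.98-fold) and Insig1 (1.64-fold). Acat2 shares 39.1% of its 50-mers and 12.1% of Tm7sf2 exons overlap another gene on the same strand. G2/M genes fell in 21 of 48 (21 adjusted over the list alone, median -0.33, adjusted p = 0.00011) and immediate early genes rose in 15 and fell in 6 (15 and 7 adjusted over the list alone, adjusted p = 0.00343). S phase genes fell in 14 and rose in 3 (adjusted p = 0.012), ribosomal protein genes fell in 13 (12 adjusted over the list alone, adjusted p = 0.012) and NF-kB genes fell in 11 and rose in 4 (adjusted p = 0.012). Their adjusted p = 0.215, 0.304, 0.174, 0.349 and 0.154 with an estimated correlation.

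BET inhibitor repressed genes (8 down, 1 up), BET proteins and P-TEFb partners (5 up, 2 down), integrins (10 down, 2 up) and fibroblast markers (6 down, 1 up) were called at adjusted p = 0.0332 each in female cells with CPI0610, and p53 targets (12 down, 5 up) at adjusted p = 0.0362. With an estimated correlation they gave adjusted p = 0.406, 0.215, 0.154, 0.265 and 0.221, and the integrin call ended without female DMSO 2 replicate 2 and female CPI0610 replicate 1, at 0.0619. Interferon-stimulated genes (10 down, 4 up, 11 and 4 adjusted over the list alone, 0.0578), X-inactivation genes (0.147), extracellular matrix genes and CDK inhibitors (0.161 each), microglia markers (0.332) and TGF-beta genes (0.565) were not called. Nor were neuron markers (0.602), glioma stem cell factors (0.674), Y-linked and mitochondrially encoded genes (0.745 each), matrix proteases (0.761), glycolysis genes (0.806), endothelial markers (0.85), stress response genes (0.86), antigen presentation genes (0.951), astrocyte markers and oligodendrocyte markers (0.974 each). For antigen presentation genes the median was 0.09 and the mean -0.18.

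For the sex difference of the CPI0610 response, Col3a1 (2.92 ± 0.17, adjusted p = 5.8e-06), Col6a3 (2.68 ± 0.2) and Col6a2 (2.59 ± 0.2) were higher in the female than in the male response. In limma on log2(RPKM + 1) Col6a3 turned to -0.388. Anxa8, an annexin, differed by 4.06 ± 0.2 and the red cell membrane gene Gypc by 3.04 ± 0.44. Stmn4 (-4.07 ± 0.68), Dhrs3 (-1.87), Synpo (-1.77) and Plau (-1.77 ± 0.15) were lower, and Igfbp5 (-1.91 ± 0.4, adjusted p = 0.023) was lost without male DMSO 2 replicate 1 or 3 or male CPI0610 replicate 1 or 3 (-1.23 without the last), at up to 0.45. Stmn4 was lost without female DMSO 2 replicate 2 (-3.39), at 0.088. Cdkn1a (-0.01 ± 0.12, adjusted p = 0.99), Hexim1 (0.09, 0.77), Brd2 (0.04, 0.95) and Myc (-0.07, 0.96) did not pass the test of the difference. Sterol synthesis genes were higher in the female response in 8 of 25 members and lower in 0 (19 and 0 adjusted over the list alone, median 0.51, adjusted p = 5.19e-19), and adjusted p = 0.00127 with an estimated correlation.

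Extracellular matrix genes (7 up, 1 down of 32, 10 and 5 adjusted over the list alone, adjusted p = 1.57e-09, and adjusted p = 0.0561 with an estimated correlation) and oligodendrocyte markers (1 up, adjusted p = 0.0223, and adjusted p = 0.209 with an estimated correlation) were the other lists called in the CPI0610 sex difference. The largest p among the 28 lists without a call was 0.979, for endothelial markers, and the smallest 0.0632, for G2/M genes. In total 220 genes were higher and 171 lower in the female CPI0610 response of 13594 tested. Without female DMSO 2 replicate 2 and female CPI0610 replicate 1, the lowest on the third component, 1263 genes were called, 380 of them among these 391, and without female CPI0610 replicate 1 alone 932. Without both, G2/M (0.000455), stress response (0.0386) and mitochondrially encoded genes (0.0295) were called too. Leaving out another library gave 204 (male CPI0610 2), 222 (male DMSO 2 replicate 3), 230 (male CPI0610 1), 231 (male CPI0610 3), 248 (male DMSO 2 replicate 2) or 249 (female CPI0610 2).

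Female and male cells in DMSO were compared in each table. In the JQ1 table Xist, the X-inactivation RNA, stood at 46.7 CPM in female and 0.276 in male cells, and Ddx3y, a Y-linked helicase gene, at 1.86 ± 2.93 and 61 ± 8.68, since 1 female library held Y-linked reads. In the table of CPI0610, Xist stood at 297 and 0.359, and Eif2s3y had 0 counts in female libraries, at least 599-fold lower than in male cells against a floor of 3 counts over the group. There Ddx3y and Kdm5d had 1 summed count each in female cells, against 4285 and 1554 in male cells. Xist shares 11.8% of its 50-mers. Y-linked genes were lower in 4 of 4 members in both tables (median -5.16, adjusted p = 0.0616 in the JQ1 table, and -10.5, adjusted p = 7.52e-27 in the CPI0610 table, adjusted p = 0.00854 with an estimated correlation). By edgeR 3473 genes were higher and 3576 lower in female cells in the JQ1 table, and 3436 and 2801 in the CPI0610 table.

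In the JQ1 table the secreted Wnt inhibitor Frzb (9.19 ± 0.29, adjusted p = 9.6e-09), the natriuretic peptide receptor Npr3, Tmem35a and Zdbf2 (8.38) were far higher in female DMSO cells, and so were the hypoxia-responsive peptide gene Adm (108-fold), smooth muscle calponin Cnn1 (131-fold) and tenascin Tnc (7.41-fold). Neto1 had 5 and Slco4a1 3 summed counts in male against 4602 and 1660 in female cells. Leaving out 1 male library took Neto1 from 9.87 to 10.5 (July-1) and Slco4a1 from 9.07 to 12.2 and Zdbf2 to 9.08 (July-2). The collagen gene Col25a1 (80.6-fold), the endothelial factor Erg (-5.54), Ces1d (-5.52), the retinoic acid carrier Crabp1 (-5.2) and the astrocyte gene Mlc1 (26-fold) were lower. The size of these rested on the female library with Y-linked reads: without it Col25a1 gave -7.69, Erg -9.67, Ces1d -7.16, Crabp1 -7.4 and Mlc1 -5.39 on the log2 scale. Myc was 1.8-fold higher in female cells (adjusted p = 0.0064), and Hexim1 lower (-0.52 ± 0.14, adjusted p = 0.011, lost without male DMSO 1 July-2 or female DMSO 1 May at up to 0.057). In the CPI0610 table Mmp2 (47.2-fold), Col6a3 (32.3-fold), the chaperone Clu (20.6-fold) and Cdkn1a (6.61-fold) were higher in female cells. Lower there were the Wnt ligand Wnt10b (719-fold, 5 against 4781 summed counts; log2 -9.39, and -11 without female DMSO 2 replicate 3), the lung and forebrain factor Nkx2-1 (559-fold), Artn (537-fold), Hmgcs1 (2.03-fold) and Pcsk9 (-2.26). Nf1 was lower in female cells in the JQ1 table (-0.44 ± 0.11, adjusted p = 0.007) and higher in the CPI0610 table (0.48 ± 0.091, adjusted p = 0.00092).

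Lists in the JQ1 table DMSO comparison were called as higher in female cells for TGF-beta and YAP genes (15 up, 4 down, 17 and 4 adjusted over the list alone, adjusted p = 0.000196), G2/M genes (23 up, 0 down, 24 and 0 adjusted over the list alone, adjusted p = 0.000296) and ribosome biogenesis genes (19 up, adjusted p = 0.000906). So were S phase genes (14 up, 1 down, 11 and 1 adjusted over the list alone, adjusted p = 0.00225), matrix proteases (12 up, 5 down, adjusted p = 0.0205) and stress response genes (14 up, 6 down, adjusted p = 0.0336). Lysosome genes (3 up, 18 down, 3 and 19 adjusted over the list alone, adjusted p = 0.00561) and astrocyte markers (1 up, 12 down, adjusted p = 0.0137) were called as lower. With an estimated correlation TGF-beta genes and proteases gave adjusted p = 0.397 each and the other 6 lists 0.872 each. Only the TGF-beta call held both with the month block and in the July libraries. In those fits the others gave, block first, 0.103 and 0.405 for S phase, 0.0824 and 0.118 for proteases, 0.067 and 0.125 for stress response and 0.0785 and 0.125 for astrocyte markers. In the July libraries G2/M genes gave 0.193, ribosome biogenesis genes 0.168 and lysosome genes 0.125, while glycolysis genes went from 0.129 to 0.0224 and 0.031.

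In the CPI0610 table extracellular matrix genes (21 up, 6 down of 32, adjusted p = 2.71e-08), matrix proteases (15 up, 3 down, adjusted p = 6.03e-08) and TGF-beta genes (18 up, 4 down, adjusted p = 0.000213) were higher in female DMSO cells, while sterol synthesis genes were lower (0 up, 18 down of 25, 0 and 18 adjusted over the list alone, median -0.81, adjusted p = 1.04e-06). Of these the sterol call held, at adjusted p = 0.0376 with an estimated correlation, and the other 3 gave adjusted p = 0.0608, 0.0608 and 0.188 with an estimated correlation. Glioma stem cell factors (16 up, 6 down, adjusted p = 0.00308), microglia markers (3 up, adjusted p = 0.00448), lysosome genes (20 up, 2 down, adjusted p = 0.00504), endothelial markers (3 up, 2 down, adjusted p = 0.0101), oligodendrocyte markers (3 up, 1 down, adjusted p = 0.0217) and integrins (12 up, 4 down, adjusted p = 0.029) were called as higher. Ribosomal protein genes (20 down, adjusted p = 0.00386), ribosome biogenesis genes (21 down, adjusted p = 0.00395), S phase genes (22 down, 2 up, adjusted p = 0.01), stress response genes (18 down, 3 up, adjusted p = 0.0121) and G2/M genes (16 down, 1 up, 13 and 1 adjusted over the list alone, adjusted p = 0.014) were called as lower. With an estimated correlation these gave, in that order, adjusted p = 0.259, 0.0608, 0.0608, 0.0693, 0.157, 0.13, 0.259, 0.128, 0.175, 0.0608 and 0.373.

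The sex differences of the DMSO sets were then set side by side. Of the genes called in each table, 1223 were higher and 978 lower in female cells in both, where independent lists would share 812 and 676, and 1171 were opposite, so that 65.3% had one direction. Across genes, which are not independent replicates, the log2 fold changes correlated at r = 0.412 (Spearman 0.168). The medians of chromosomes 2 and 15, given above, differed between the sets. In the fit of all 24 libraries 3364 genes had a larger and 2829 a smaller female minus male difference in set 2 than in set 1. Cdkn1a (3.05 ± 0.212, adjusted p = 6.12e-10), Col6a3 (5.6 ± 0.368) and Clu (5.81 ± 0.269) were among the first, and Cnn1 (-7 ± 0.259) and Hmgcs1 (-1.27 ± 0.137) among the second. S phase (25 down, 32 adjusted over the list alone, adjusted p = 3.87e-06), G2/M (33 down, 37 adjusted over the list alone, adjusted p = 5.9e-07) and sterol synthesis genes (16 down, 17 adjusted over the list alone, adjusted p = 1.12e-05) were lower and lysosome genes higher (24 up, adjusted p = 5.9e-07), with adjusted p = 0.485, 0.483, 0.183 and 0.356 with an estimated correlation. Between the sets, 9043 genes differed in male and 7257 in female cells, a contrast added after the data were seen. Library totals moved the all-gene median of the male contrast to -0.21 and that of the sex difference to 0.14.

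Under the drugs, female and male cells differed in 3622 genes up and 3308 down with JQ1 and in 3475 up and 3034 down with CPI0610. S phase genes were higher in female cells in 36 of 40 under JQ1 (37 up and 2 down adjusted over the list alone, median 1.73, adjusted p = 1.19e-07) and G2/M genes in 38 of 48 (41 adjusted over the list alone, adjusted p = 1.62e-08), both with adjusted p = 0.722 with an estimated correlation. Sterol synthesis genes were higher in 18 and lower in 1 of 25 under JQ1 (19 and 1 adjusted over the list alone, median 0.93, adjusted p = 2.14e-06, and adjusted p = 0.423 with an estimated correlation), while under CPI0610 4 were higher and 9 lower (adjusted p = 0.254). Under CPI0610 extracellular matrix genes were higher in 22 and lower in 5 of 32 (median 0.83, adjusted p = 9.68e-14, and adjusted p = 0.0174 with an estimated correlation) and G2/M genes were lower in 35 and higher in 1 (37 and 1 adjusted over the list alone, adjusted p = 0.000746, and adjusted p = 0.234 with an estimated correlation). With the month block 5 list calls under JQ1 changed: BET inhibitor repressed genes went from 0.0394 to 0.152, ribosome biogenesis genes from 0.0313 to 0.165, proteases from 0.0377 to 0.0701, Y-linked genes from 0.0298 to 0.167 and integrins from 0.123 to 0.048. In the July libraries the first 4 gave 0.251, 0.421, 0.0773 and 0.0773.

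Genes chosen as sex-biased by at least 2-fold in the DMSO set of the other table were followed through each drug. The 1430 female-biased genes differed by 0.89 on the log2 scale between female and male cells in DMSO set 1 and by 1.25 under JQ1, a mean change of 0.36 that did not pass limma's fry test (adjusted p = 0.0799 over the 2 sets of genes, 0.04 before adjustment). It passed without male DMSO 1 July-1 (0.42, adjusted p = 0.00446) or female JQ1 May (0.36, adjusted p = 0.0384). The change was 0.2 with no 2-fold minimum and -0.000561 with genes chosen in the same table. The 468 male-biased genes went from -1.3 to -1.15 (adjusted p = 0.285), and without female DMSO 1 July-1 their change was 0.42 (adjusted p = 0.00342). Under CPI0610 1259 female-biased genes went from 1.38 to 1.32, a change of -0.06 (adjusted p = 0.0292). The 1488 male-biased genes of set 1 went from -0.05 to 0.09, a change of 0.14 (adjusted p = 0.00431). Their mean held almost no male bias to lose in set 2. The call for female-biased genes was lost with other size factors (adjusted p = 0.349), and in 5 of 12 runs without 1 library, at up to 0.0758. With genes chosen in the same table, at 4-fold and with no 2-fold minimum, the change of male-biased genes was 0.481, 0.00554 and 0.033 under JQ1 and 0.398, 0.223 and 0.0633 under CPI0610. Choice in the same table moves the change against the bias by itself, since its DMSO libraries enter both. Unadjusted camera p-values, with the preset and an estimated correlation, were 3.46e-05 and 0.172 for female-biased and 0.232 and 0.602 for male-biased genes under JQ1. Under CPI0610 they were 0.273 and 0.176, and 0.000637 and 0.0102. Single genes went both ways: of the female-biased genes 97 rose and 22 fell in the JQ1 interaction, and 36 rose and 48 fell in that of CPI0610.

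Both inhibitors were compared with each other, with the limit that JQ1 at 500 nM and CPI0610 at 1 µM differ in dose and in DMSO set, so drug, dose and set cannot be told apart. In male cells 1457 genes rose with both and 1770 fell with both, where independent lists would share 514 and 644, and 85 went opposite ways among 13112 genes. In female cells the numbers were 1470, 1623 and 19, against 400 and 497. Across genes the responses correlated at r = 0.736 in male and 0.792 in female cells. Hexim1 rose 2.7-fold with JQ1 and 2.82-fold with CPI0610 in male cells (difference -0.06 ± 0.173, adjusted p = 0.922) and 3.63-fold and 3.02-fold in female cells (0.25 ± 0.174, 0.678). Brd2 differed by 0.47 ± 0.178 in male and 0.45 ± 0.178 in female cells (adjusted p = 0.113 and 0.289). Cdkn1a differed in female cells by 1.27 ± 0.209 (adjusted p = 0.00177), where it fell with CPI0610 and did not pass the test with JQ1. Between the sexes, 1501 genes rose and 1815 fell in both with JQ1 (chance 394 and 567) and 1846 and 2082 with CPI0610 (chance 488 and 626).

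The JQ1 response minus the CPI0610 response in male cells was positive for 347 and negative for 781 genes by edgeR, 30.8% positive, and 18.8% with library totals. With the month block 2195 and in the July libraries 1659 genes were called. Without male CPI0610 2 or 3 or male DMSO 2 replicate 2 or 3 the counts were 728, 729, 749 and 742. Egfr (-1.73 ± 0.149, adjusted p = 2.13e-06), Itgb3 (-2.07 ± 0.232) and the matrix gene Tgfbi (-3.56 ± 0.464) were lower in the JQ1 response, and Sox11 (1.27 ± 0.185) and Wdr74 (0.72 ± 0.134) were higher. G2/M genes were lower in 6 (14 adjusted over the list alone, median -0.94, adjusted p = 7.24e-12), sterol synthesis genes in 9 (12 adjusted over the list alone, adjusted p = 2.09e-07), and interferon-stimulated genes in 7 (10 adjusted over the list alone, adjusted p = 2.09e-07). Also lower were astrocyte markers in 6 (7 adjusted over the list alone, adjusted p = 5e-06), integrins in 6 (7 adjusted over the list alone, adjusted p = 3.85e-05) and S phase genes in 1 (adjusted p = 6.26e-08). Ribosome biogenesis genes were higher in 6 (8 adjusted over the list alone, median 0.39, adjusted p = 2.09e-07). In that order the lists gave adjusted p = 0.437, 0.11, 0.11, 0.11, 0.0834, 0.55 and 0.437 with an estimated correlation. BET inhibitor induced genes were not called (median -0.27, adjusted p = 0.483).

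In female cells the difference between the inhibitors was positive for 43 and negative for 211 genes, with 538 calls under the month block and 443 in the July libraries. Without 1 library the counts were 119 (female JQ1 July-2), 122 (female DMSO 1 July-1), 140 (female DMSO 2 replicate 2), 156 (female DMSO 2 replicate 1), 159 (female CPI0610 2), 162 (female DMSO 2 replicate 3) and 447 (female CPI0610 1). p53 targets were higher in the JQ1 response in 2 of 26, Btg2 (1.15 ± 0.183) and Cdkn1a (8 adjusted over the list alone, median 0.36, adjusted p = 9.64e-08), and adjusted p = 0.00225 with an estimated correlation. Btg2 is an antiproliferative gene, and Trp53 gave counts in every group although the cells are labelled as lacking p53. Matrix proteases were lower in 3 of 21 (7 adjusted over the list alone, adjusted p = 3.28e-06, and adjusted p = 0.00897 with an estimated correlation), led by Adam12 (-1.8 ± 0.204). Interferon-stimulated genes (adjusted p = 0.000106), extracellular matrix genes (adjusted p = 0.000121) and sterol synthesis genes (adjusted p = 0.000535) were called as lower, with adjusted p = 0.247, 0.247 and 0.269 with an estimated correlation.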

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

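The tests of the starting level of the sterol genes and of Y-linked and male-specific transcripts, and the draws within months, were chosen only after the result was seen, and the others were written before.

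Results were picked out because an edgeR test of the difference between groups itself called genes: 497 in the sex difference of the JQ1 response, 391 in that of CPI0610, 1128 and 254 in the JQ1 response minus the CPI0610 response in male and female cells, and 6193 between the sex differences of the DMSO sets. The genes named for the JQ1 sex difference by the rule set beforehand were Col6a3 (5.06), Rnase4 (5.06), Lgals9 (4.19), Adcy8 (4.11, but -0.552 in limma on log2(RPKM + 1)) and Epha3 (3.5), higher in the female response. Plau (-2.45), Nr2f1 (-2.57), Mylk (-2.36), Fhod3 (-2.25) and Adamtsl1 (-2.21) were lower. In the CPI0610 sex difference they were Col6a3 (2.68, but -0.388 in limma on log2(RPKM + 1)), Col3a1 (2.92), Col6a2 (2.59), Anxa8 (4.06) and Gypc (3.04), higher, and Igfbp5 (-1.91), Plau (-1.77), Stmn4 (-4.07), Dhrs3 (-1.87) and Synpo (-1.77), lower.

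For the comparisons of 3 libraries with 3, 10 splits are too few for a share under 0.05. The true grouping was the highest, 1 of 10, in each: 5883 genes for JQ1 in male and 4778 in female cells, 7049 and 6930 for sex in DMSO and under JQ1, 5651 and 5339 for CPI0610 in male and female cells, and 6237 and 6509 for sex in DMSO and under CPI0610. The highest other split called 0 genes in all 8.

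With 100 label draws and limma counts, the true grouping was highest for the JQ1 sex difference (613 genes, highest other 33, 1 of 100). It was also highest for the inhibitor difference in male cells (1299, highest other 2, 1 of 100). The same held in female cells (140, highest other 1, 1 of 100). It also held for the sex differences of the DMSO sets (5988, highest other 1507, 1 of 100). These draws left out the month. With the month in the model and labels redrawn within months, the true grouping was again highest. It called 1510 genes for the JQ1 sex difference (highest other 1, 1 of 72). The inhibitor difference in male and female cells gave 2786 and 392 (highest other 112 and 6, 1 of 100 each). The DMSO sets gave 6964 (highest other 8, 1 of 100). Redrawn splits mix the true groups, which lowers their calls. Each sex came from 1 preparation, so chance differences between preparations stay open. For the CPI0610 sex difference 2 of 100 draws, the true one with 467 genes included, reached the true count. The other called 817 genes on exchanging female DMSO 2 replicate 3 and female CPI0610 replicate 1, which points to structure among these samples.

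Y-linked transcripts were found in female DMSO 1 July-1 at 7.77% (Ddx3y), 7.64% (Eif2s3y), 7.1% (Kdm5d) and 7.04% (Uty) of the male level, median 7.37%. A label exchanged with a male library would give a level near that of male cells, so 7.37% argued against it. Male-specific genes on other chromosomes stood at a median of 9.22% in that library (Nkx2-1 8.37%, Wnt10b 10.1%, Rasgrf1 7.49%, Artn 10.2%). Male cells or male RNA in the library is thus a possible explanation, which stays open. No biological explanation was tested.

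Ribosomal protein genes were higher in the May libraries in 42 of 44 members (median 2.49). The month difference of the listed genes followed the share of their 50-mers found in other genes (Spearman 0.554), and among other genes those sharing over 50% stood 1.08 above those sharing under 5%. Reads shared between near-identical copies and counted differently by month could account for this. Listed genes sharing under 10% still had a median of 0.606, so higher levels in the cells could also account for part. Both stay open.

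The sterol synthesis list was called in the sex difference of both responses, but with an estimated correlation the JQ1 call was lost (adjusted p = 0.218) and only the CPI0610 call was kept (adjusted p = 0.00127). The female minus male DMSO difference was 0.0917 in the JQ1 and -0.807 in the CPI0610 table, which cannot tell whether the starting level matters, since the same DMSO libraries enter the response. A single library was argued against, since the lowest median difference without 1 library was 0.831 of the full one. The month or the libraries left out in doubt were argued against, at 0.973. Sex or the single preparation per sex stays open, as each sex came from 1 preparation.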

How the results depend on the processing

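The month block, the July libraries alone, the fit without female DMSO 1 July-1, the fit without 2 female libraries, the block of the number and month in the JQ1 columns and the adjustment of fry over 2 sets were chosen only after the result was seen. Simulated 2-fold sex differences of a response were recovered in 16% of cases for JQ1 and 85% for CPI0610, and what depth limits was not tested. The cause of each change below was not tested, except that a stricter threshold leaves fewer calls by construction. A stricter filter and library totals moved none of the 15 counts by over 1.5 times. The gene list calls were the same in 306 of 310 with other size factors and in 204 with an estimated correlation, where 106 were lost. With other size factors ribosome biogenesis genes (JQ1, female cells, 0.046), astrocyte markers (JQ1 sex difference, 0.0494) and p53 targets (DMSO, CPI0610 table, 0.047) were gained and fibroblast markers (CPI0610, male cells, 0.0507) lost. Without the 2 female libraries p53 targets in DMSO (0.0465) and immediate early genes under CPI0610 (0.0262) were gained, and microglia (0.0943) and endothelial markers (0.0511) under CPI0610 lost. With the month block and without female DMSO 1 July-1, astrocyte markers (JQ1 sex difference, 0.0311) and Y-linked genes (DMSO, 2.76e-16) were gained beyond the changes of the block alone.

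At least 2-fold left 2478 of 5883 calls for JQ1 in male and 1906 of 4778 in female cells, 294 of 497 for their difference, 1501 of 5651 and 1319 of 5339 for CPI0610 and 150 of 391 for its sex difference. It left 3329 and 3320 for sex in DMSO and under JQ1, 2075 and 2124 beside CPI0610, 572 and 165 for the inhibitor difference in male and female cells and 3439 for the DMSO sets. Adjusted p under 0.01 left 3679 and 2908 for JQ1, 119 and 153 for the sex differences and 465 and 88 for the inhibitor differences. Genes moved alike by both inhibitors went from 3227 in male cells to 965 at 2-fold and 1944 at 0.01, and from 3093 in female cells to 853 and 1784.

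The JQ1 sex difference gave 310 genes with no filter, 1098 by DESeq2, 1198 and 911 by limma on log2(RPKM + 1) and log2(RPKM + 0.1), 1629 with the month block and 1118 with it and without female DMSO 1 July-1. That of CPI0610 gave 621 by DESeq2, 794 by limma on log2(RPKM + 1) and 1263 without the 2 female libraries, and CPI0610 in female cells 3305 with only the groups compared. The inhibitor difference in male cells gave 643 with no filter, 1767 by DESeq2 and 2195 with the month block, and in female cells 145, 485 and 538, with 443 in the July libraries. On simulated male responses 16.6% (JQ1) and 14.6% (CPI0610) of DESeq2 calls were false, against 4.57% and 7.48% by edgeR.

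The mean change under JQ1 of female-biased genes, 0.357, was 0.396 and passed the test at 4-fold. That of male-biased genes, 0.154, passed the test when female DMSO 1 July-1 was left out and the month was a block (0.433), but not with the block alone (0.161). The CPI0610 change of female-biased genes, -0.0597, did not pass with genes chosen in the same table (-0.0878), at 4-fold (-0.123), with other size factors (-0.0349) or without the 2 female libraries (-0.0521), while that of male-biased genes (0.138) passed in each. The same-table pass is no evidence, since its DMSO libraries enter the change.

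Direction turned for Adcy8, sex difference in the JQ1 response, in limma on log2(RPKM + 1) (-0.552) and log2(RPKM + 0.1) (-0.474), and for Tmem119 in that difference with 1 added (-0.187). With 1 added it also turned for Tmem119, sex difference in the CPI0610 response (-0.795), and there for Col6a3 (-0.388), Mlc1 (-0.737) and Slc1a3 (0.138).

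Leaving out 1 library gave 4532 to 5407 genes for JQ1 in male and 3415 to 4192 in female cells, 5622 to 7447 and 5893 to 6425 for sex in DMSO and under JQ1, 4647 to 4923 and 4408 to 6502 for CPI0610, 5095 to 6865 and 5375 to 8085 for sex beside it and 5431 to 6784 for the DMSO sets. The JQ1 sex difference ranged from 207 (female JQ1 July-2) to 683. The CPI0610 sex difference ranged from 204 (male CPI0610 2) to 932 (female CPI0610 1). The inhibitor difference ranged from 728 (male CPI0610 2) to 1567 in male cells. In female cells it ranged from 119 (female JQ1 July-2) to 447 (female CPI0610 1).

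The mean change of sex-biased genes, leaving out 1 library, ranged for female-biased genes under JQ1 from 0.22 to 0.426. For male-biased genes it ranged from 0.0869 to 0.422. Under CPI0610 it ranged from -0.104 to -0.0237 for female-biased genes, whose call was lost without male DMSO 2 replicate 2 (-0.0763) or 3 (-0.0788), male CPI0610 1 (-0.0237), female DMSO 2 replicate 1 (-0.0472) or female CPI0610 3 (-0.0626), and from 0.0888 to 0.162 for male-biased genes.

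With the replicate number as a block the CPI0610 sex difference gave 255 genes, and list calls were gained for mitochondrially encoded genes there (0.0894 to 0.0406) and, for sex in DMSO, for p53 targets (0.0553 to 0.0477) and X-inactivation genes (0.199 to 0.0477). Named genes whose calls were lost with the block were Myc (male response, 0.06), Cspg4 (female response, 0.052), Brd2 (sex in DMSO, 0.061) and, in the sex difference in the CPI0610 response, Igfbp5 (0.061), Slc1a3 (0.066), Ddit4 (0.066), Relb (0.068), Optn (0.073), Bhlhe40 (0.081), Ankrd1 (0.082), Sdf2l1 (0.088), Tpm1 (0.091), Pfkp (0.097) and Map2 (0.1). The block changed no other list or named-gene call, but the other gene counts fell. The numbers in the JQ1 columns are not tied to the replicate numbers of the labels. As a block together with the month they gave 1547 genes for the JQ1 sex difference and 2307 and 568 for the inhibitor difference in male and female cells, and no other count moved by over 1.5 times. Of 155 list calls 8 were lost and 4 gained with that block. Libraries of one July number correlated best in male cells (0.653 and 0.617 against 0.251 and 0.308) but not between the sexes in DMSO (male July-1 at 0.241 with female July-1 and 0.29 with July-2).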

Other observations

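The contrasts between the DMSO sets within each sex were chosen only after the result was seen. In male cells DMSO set 2 was compared with set 1, where set, table and month cannot be told apart. Ribosome biogenesis genes were higher in set 2 in 34 of 36 members and lower in 0 (34 and 0 adjusted over the list alone, median 1.56, limma camera adjusted p = 2.4e-19, and adjusted p = 0.154 with an estimated correlation), among them the nucleolar methyltransferase Nop2 (1.93 ± 0.124). Astrocyte markers were lower in 18 of 21 and higher in 1 (median -3.21, adjusted p = 7.77e-07, and adjusted p = 0.154 with an estimated correlation), and Clu was lower (-3.42 ± 0.197).

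In female cells Clu was higher in set 2 (2.39 ± 0.183) and the calponin Cnn1 lower (-5.03 ± 0.195), while Nop2 was 0.88 ± 0.121 higher. Targets of p53 were higher in 17 of 26 and lower in 2 (18 and 2 adjusted over the list alone, median 0.618, adjusted p = 5.6e-05, and adjusted p = 0.0278 with an estimated correlation).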
